A study of Mus musculus with 78 samples.

How the data were processed

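RNA was measured from the gonads of C57BL/6 mice, an inbred laboratory strain, that were fed ad libitum. Per the labels' protocols, about 5 ug of total RNA per mouse was extracted with silica columns after bead disruption, copied into cDNA with 33P-dCTP, a radioactive nucleotide, and hybridised to a 17K mouse cDNA clone set. The clones lie on a pair of membranes, A and B, with 8448 spots each, and each mouse has 1 array on each membrane. The 39 mice fall into 9 classes of sex and age taken from the labels, and each mouse is a separate animal.

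The deposited values are standardized scores that the authors had already scaled within each array. In every column the mean was 0 and the standard deviation 1, so that a value gives the distance from the array's mean in standard deviations of that array. The scale before standardizing, its log base and any background correction are not given in the sources used here. Differences are therefore in z-score units of the deposited scores, and no fold change can be formed. Spots carry no counts, so the number of arrays limits the precision. An increase in some spots lowers the others of the same array by construction, and every difference is relative to the rest of its membrane.

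Spots were named from the platform annotation, which can be old. Of 16896 spots, 9663 had 1 gene symbol, 436 had several and 6797 were not listed, so 7233 clones stayed unnamed here. Entrez identifiers matched 9641 of the named spots to the gene table of GRCm38.p6, whose symbols were then used, and the others kept the annotation's symbol. Coordinates are not printed because the annotation names no build. A feature was a gene symbol, with its clones on a membrane averaged, or an unnamed clone. A gene on both membranes was taken from the membrane with more of its clones, with ties going to A, and 963 genes were on both. This gave 14384 features, 7151 of them named, and 1226 genes had more than 1 clone.

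How far a name can be trusted was checked with pairs of clones of the same gene. Over 713 such pairs on membrane A the sex difference correlated across genes with r = 0.304, over 561 pairs on membrane B with r = 0.207, and between the membranes over 963 genes with r = 0.146. The mean levels correlated with r = 0.0917, 0.106 and 0.0200. Genes are not independent replicates, so these values describe the clones only. After these low values had been seen, the list of names was shifted along the spots of each membrane. The unshifted names gave the highest agreement, with r = 0.304 on membrane A against at most 0.181 over 8447 other shifts, and r = 0.207 on membrane B against at most 0.197. A value for a gene is therefore the value of the clones that carry its name.

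Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the deposited scores, each membrane fitted on its own. P-values were adjusted by the Benjamini-Hochberg method over the 14384 features of both membranes together, with a threshold of 0.05. The sex difference was the mean of adult males minus that of adult females over 3 adult age classes, with 30 mice and 6 class means. Age trends were linear slopes per year of age, fitted in 15 adult males, in 15 adult females and, for the difference between the slopes, in all 30. The maturation steps of the testis were fitted over 20 males, and that of the ovary over 19 females, so that all classes of a sex shared a spread. The last comparison was the slope on age over all 39 mice with sex as a covariate.

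Gene lists were tested with camera at its preset correlation of 0.01 on the moderated statistics, again with an estimated correlation, and with fry for direction, with Benjamini-Hochberg adjustment over the lists of a comparison. Of 33 lists, 30 had at least 3 measured members. Those for B and plasma cells, T and NK cells, and epididymis and accessory ducts had too few, with 2, 0 and 1 measured members, and were not tested. The lists of ribosomal proteins, oxidative phosphorylation, proteasome and chaperones were symbol patterns. The ribosomal pattern also took in the kinase genes Rps6ka3, Rps6ka5, Rps6ka6 and Rps6kc1, and that of oxidative phosphorylation took in assembly factors such as Ndufaf3. Counts of members are given over all features and adjusted over the list alone. After the data were examined, per-mouse list means were also compared by exact 2-sided permutation tests for 10 lists that camera had called in any comparison. The groups, comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined.

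The rule named, for each comparison, the 10 largest increases and 10 largest decreases among passing genes with a symbol, leaving out RIKEN, EST and similar clone names. Where fewer than 5 features passed, it named the 5 with the smallest p in each direction. Up to 4 members with the smallest p were named per list, and Xist with the Y-linked genes served as a check of the labels.

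The procedure was tested on simulated data in which 200 of 14384 features were shifted. The noise was drawn once per comparison and independently for each feature, so features did not move together and no array stood apart. The shares below hold for that setting and can differ in the real data. For the sex difference it recovered 50.0% of shifts of 0.25 z-score units and 93.9% of shifts of 0.5. For the slopes on age these sizes are z-score units per year, so their shares cannot be set beside those of the class differences. For the male age trend the procedure recovered 79.4% and 98.5%, and for the female age trend 26.5% and 75.8%. For the difference of the slopes the values were 19.1% and 72.7%. For 40-44-day against 17-19-day males they were 5.88% and 72.7%, and for 174-194-day against 40-44-day males 23.5% and 83.3%. For females of 169-194 against 17-33 days they were 1.47% and 37.9%, and for the slope over all mice 94.1% and 98.5%. Among the calls, 1.47% to 6.67% were false, so some comparisons lay above the nominal 5%. The draw of features depends on their sort order, and another order moved these percentages by a few points.

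Among 741 pairs of arrays per membrane no pair held identical values, and the highest correlations were 0.990 on membrane A and 0.988 on membrane B. The 714-day male (males of 714-743 days, replicate 2) carries a description that names a male of 43 days, so its age is in doubt. It was kept under its title and characteristics, and was also left out in turn. The numbers in the titles run in 5 serial sets with about 1 mouse of each adult class, and these were tried as a block. Males of 17-19 days are only in sets 3 and 4, and those of 40-44 days only in sets 1, 2 and 5. No set holds both, so these 2 classes are confounded with the set. Within a set the numbers rise with the age class. Other alternatives were quantile normalization, scaling by the median and median absolute deviation, a filter on dim features, single clones, a trended robust eBayes step, array weights, a spread shared by all mice, the oldest against the youngest adult class, the logarithm of age, and leaving out each mouse. The 481-day female (females of 476-499 days, replicate 4), whose arrays stand apart, was left out as an alternative chosen after seeing the data.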

Results

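Gonads of 39 C57BL/6 mice were profiled on clone arrays to compare ages and sexes. Males gave testes and females ovaries. There were 2 males of 17-19 days, 3 of 40-44 days, and 5 each of 174-194, 476-498 and 714-743 days. Females numbered 4 at 17-33 days, and 5 each at 169-194, 476-499 and 704-733 days. Values are z-scores, in standard deviations of an array, and each value below is a difference in these units ± its standard error unless stated. Arrays of the same sex resembled each other closely, with median correlations across spots of 0.960 to 0.981 for males and 0.934 to 0.957 for 18 females on membrane A. With arrays of the other sex the medians were 0.881 to 0.935 for males and 0.867 to 0.948 for these females. For the females the ranges overlap, so this correlation does not by itself separate the sexes. The 481-day female stood apart, at 0.698 on membrane A and 0.749 on membrane B, and counts are also given without it.

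**Figure D1:**
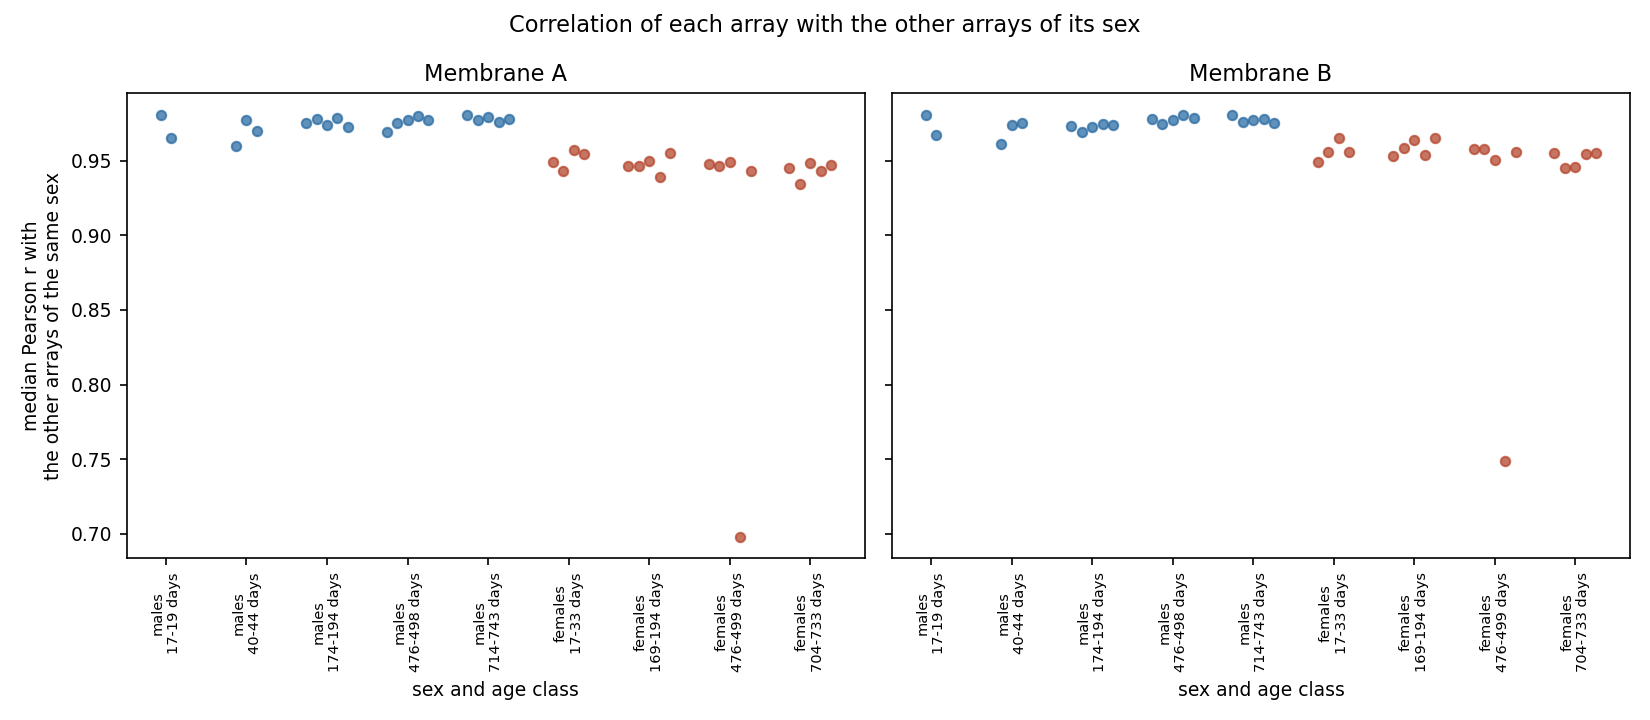
Median Pearson r (vertical axis) of each array with the other arrays of the same sex, by sex and age class (horizontal axis), for membranes A and B. Each point is 1 array, blue for males and red for females, and the lowest points are the 481-day female at 0.698 and 0.749.

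The first comparison asked how adult testis and ovary differ. As a check of the labels, Xist, the RNA that silences an X chromosome in females, was lower in males by an estimate of -0.53 ± 0.08 (adjusted p = 8.73e-06), and all 15 females lay above the male mean. Eif2s3y, a Y-linked translation factor, was higher in males by 0.25 ± 0.06 (adjusted p = 0.00180). Uty, a Y-linked demethylase gene, went the other way, at -0.30 ± 0.07 (adjusted p = 0.00105). Its levels were -1.92 ± 0.16 in males and -1.62 ± 0.24 in females (SD, n = 15 each). On these clones the Y-linked genes did not share a direction.

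The largest testis-high value belonged to Cep57, which encodes a centrosomal protein, with -0.83 ± 0.21 in adult males and -2.76 ± 0.45 in adult females (SD, n = 15 each), a difference of 1.92 ± 0.12 (adjusted p = 8.18e-13). Ran, the GTPase that drives nuclear transport, differed by 1.54 ± 0.07 and the nucleolar gene Lyar by 1.59 ± 0.06. Vasn, a membrane protein that binds TGF-beta, differed by 1.65 ± 0.06, the ubiquitin ligase gene Rnf19a by 1.61 ± 0.11 and the sialyltransferase gene St6galnac2 by 1.52 ± 0.07. The exonuclease gene Exd2 (1.49 ± 0.05), Pebp1 (1.41 ± 0.07), the actin-binding thymosin gene Tmsb10 (1.32 ± 0.09) and the glutathione transferase gene Gstm5 (1.32 ± 0.10) completed the 10 largest, and for each of them all 15 males lay above the female mean. Among ovary-high genes, Jag1, a Notch ligand, had the largest difference at -1.60 ± 0.18 (adjusted p = 2.10e-08), with 0.43 ± 0.41 in males and 2.03 ± 0.62 in females (SD, n = 15 each). Ccdc192 followed at -1.49 ± 0.18, then Cptp, a ceramide-1-phosphate carrier, at -1.48 ± 0.33, and the actin-bundling Pls1 at -1.44 ± 0.15. Msantd1 (-1.42 ± 0.16), Tmem168 (-1.38 ± 0.30), the zinc finger gene Zkscan1 (-1.37 ± 0.17), the kinase gene Map3k7 (-1.34 ± 0.16), the Golgi mannosidase gene Man2a2 (-1.26 ± 0.15) and Pigq (-1.23 ± 0.26), of glycolipid anchor synthesis, were also higher in ovary. Most of these names rest on 1 clone each.

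**Figure D2:**
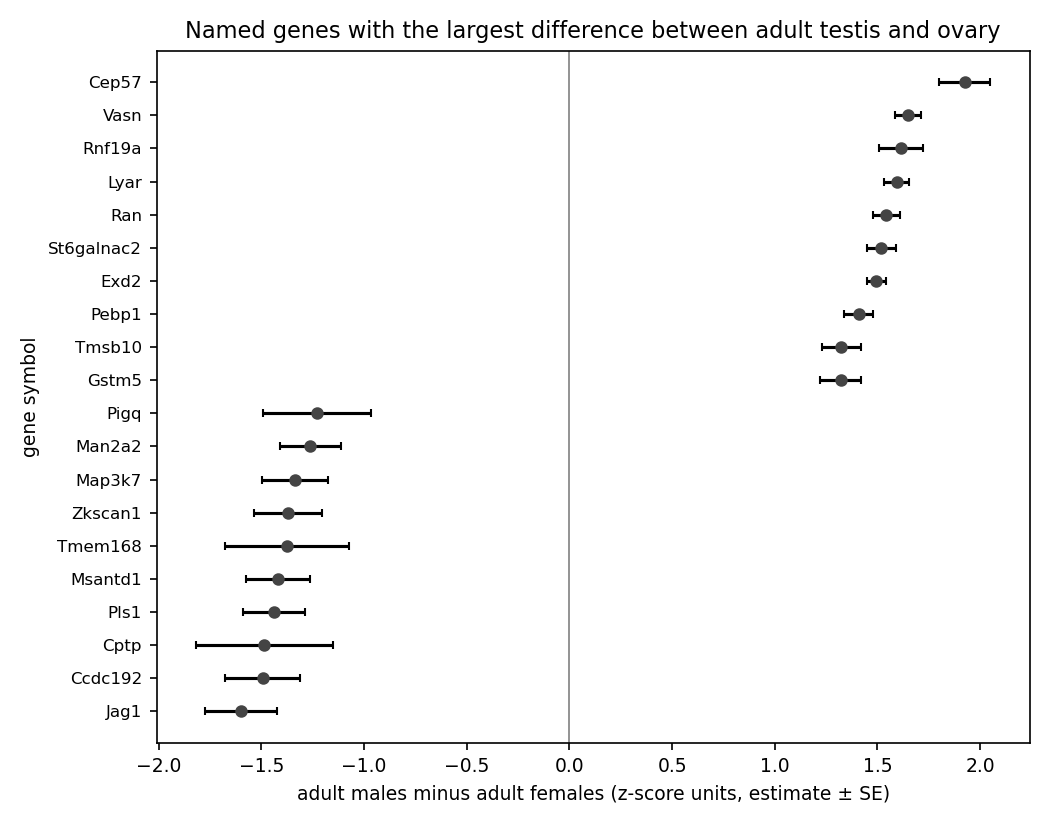
Adult male minus adult female difference (horizontal axis, z-score units) for the 20 named genes with the largest passing differences (vertical axis); points are limma estimates and bars their standard errors, from 15 males and 15 females. Cep57 has the largest positive value, 1.92, and Jag1 the largest negative one, -1.60.

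In all, 6054 of 14384 features passed, 3066 higher in testis and 2988 higher in ovary, with a median size of 0.258 among them. Without the 481-day female 9095 passed, 4458 higher and 4637 lower, and 6038 of the 6054 were among them. Scaling by the median and median absolute deviation changed the balance from 50.6% to 35.9% higher in testis, with 2313 higher and 4138 lower, so the shares in each direction depend on the scaling.

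Spermatid and sperm genes were higher in testis as a group, with 7 of 9 measured members passing, also 7 when adjusted over the list alone, and none lower. They included the kinase anchor gene Akap1 (0.66 ± 0.04), the flagellar gene Tekt2 (0.55 ± 0.07), Mea1 (0.39 ± 0.04) and the spermatid antizyme gene Oaz3 (0.38 ± 0.05). Camera gave an adjusted p = 0.00172, and an adjusted p = 0.0304 with an estimated correlation. Without the 481-day female the latter was adjusted p = 0.0945. Lysosomal genes leaned to ovary, with 11 of 33 lower in testis and 4 higher, the same counts when adjusted over the list alone. Psap, the precursor of sphingolipid activators, differed by -0.49 ± 0.06, Cd63 by -0.45 ± 0.06, the proton pump subunit gene Atp6ap1 by -0.44 ± 0.06 and Lamp2 by -0.31 ± 0.04. The list had an adjusted p = 0.0207 and an adjusted p = 0.0304 with an estimated correlation, but adjusted p = 0.0638 without the 481-day female, and it was not called without the dimmest features.

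Lists of general cell functions were also higher in testis at the preset correlation. Of 62 chaperone genes 34 were higher and 6 lower (36 and 6 adjusted over the list alone), among them the heat shock gene Hsp90aa1 (0.99 ± 0.06) and its partner Bag5 (0.91 ± 0.04), with an adjusted p = 2.42e-06 and adjusted p = 0.177 with an estimated correlation. Of 67 genes of oxidative phosphorylation 44 were higher and 2 lower (45 and 2 adjusted over the list alone), led by Ndufaf3 (0.70 ± 0.04) and Ndufa13 (0.44 ± 0.03), with an adjusted p = 4.03e-05 and adjusted p = 0.344 with an estimated correlation. The proteasome had 17 of 38 higher and 1 lower, alone or over all features, with Psma6 at 1.08 ± 0.08 and Psmc2 at 0.94 ± 0.06. Its adjusted p = 0.0212 became adjusted p = 0.294 with an estimated correlation. Cell cycle genes had 34 of 70 higher and 7 lower, also adjusted over the list alone, with tubulin Tuba1b at 1.15 ± 0.07 and the replication helicase gene Mcm3 at 0.54 ± 0.04. Their adjusted p = 0.0207 became adjusted p = 0.294 with an estimated correlation, and they were not called without the dimmest features.

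Luteal genes had an adjusted p = 0.0420 towards ovary, and adjusted p = 0.517 with an estimated correlation, although 2 of 7 were higher and 2 lower. Their mean was -0.114 and their median -0.00200. The steroid dehydrogenase gene Hsd3b1 was lower in testis at -1.21 ± 0.05, while Star, which carries cholesterol into mitochondria, was higher at 0.62 ± 0.09. The luteal call was also lost with quantile normalization, scaling by the median and median absolute deviation, or array weights, and without 7 other single mice in turn. Without the 481-day female the list had an adjusted p = 0.0686, so 5 lists remained called, none of them with an estimated correlation.

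The other cell type lists were not called by camera, while fry called 22 of all 30 lists in this comparison. Of all 7151 named genes, 1947 passed higher in testis and 1109 lower, and the counts of this paragraph are to be read beside that share. Members higher and lower in testis were 3 and 0 of 11 for spermatogonia, 7 and 3 of 15 for meiotic spermatocytes, 3 and 2 of 17 for Sertoli cells, and 2 and 1 of 8 for Leydig cells. They were 7 and 2 of 25 for oocytes, 5 and 1 of 15 for granulosa cells, 2 and 1 of 14 for theca and stroma, and 3 and 3 of 10 for ovarian surface cells. The oocyte genes Ooep (0.31 ± 0.03), Btg4 (0.22 ± 0.05) and Gdf9 (0.16 ± 0.04) were higher in testis on these clones, and the activin subunit gene Inhba was lower at -0.86 ± 0.15. Counts were 2 and 3 of 14 for macrophages, 4 and 2 of 9 for smooth muscle, 1 and 2 of 6 for endothelium, 0 and 0 of 4 for adipocytes, 4 and 2 of 12 for oviduct and uterus, and 1 and 0 of 8 for red blood cells. Among other lists they were 1 and 1 of 13 for cholesterol synthesis, 6 and 3 of 13 for MHC and interferon, 3 and 3 of 12 for complement, 4 and 7 of 28 for collagens and matrix, and 26 and 7 of 71 for ribosomal proteins. They were 14 and 6 of 30 for antioxidant genes, 9 and 2 of 25 for DNA damage genes, 3 and 5 of 17 for insulin signalling, and 1 and 2 of 3 for the Y-linked and X-inactivation list. For spermatogonia the mean of 0.0814 and the median of -0.0267 had opposite signs. For theca and stroma the mean was 0.0201, with the median of -0.0177 and the test pointing to ovary, and for complement (mean 0.0194) and endothelium (mean 0.0163) the test also pointed to ovary. Counts adjusted over the list alone differed for Sertoli cells (3 and 1), Leydig cells (2 and 2), oocytes (7 and 1), MHC and interferon (6 and 4), complement (4 and 3) and ribosomal proteins (27 and 7), and for the other lists of this paragraph they did not.

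The second comparison followed adult testis from 174 to 743 days. Erdr1, an erythroid differentiation regulator gene, fell by 0.317 per year (SE 0.047, adjusted p = 0.0400) and was the only feature that passed. Its level was -0.48 ± 0.14 at 174-194 days, -0.72 ± 0.12 at 476-498 days and -0.96 ± 0.07 at 714-743 days (SD, n = 5 each). The next smallest p-values belonged to Alad, of haem synthesis (-0.17 ± 0.04), the complement gene C1qa (-0.12 ± 0.03), Haus8 (-0.19 ± 0.05) and Klf9 (-0.13 ± 0.03) with negative slopes. With positive slopes they belonged to Cdc14b (0.33 ± 0.10), Pnma2 (0.16 ± 0.05), Smim8 (0.13 ± 0.04), Nsl1 (0.10 ± 0.03) and Avl9 (0.13 ± 0.04), and none of these 9 passed (adjusted p = 0.603). At an unadjusted p under 0.05 there were 1136 features against 719.2 by chance. When single males were left out in turn, 1 feature passed without replicate 3 of 174-194 days, replicate 4 of 476-498 days or replicate 1 of 714-743 days, 2 passed without replicate 1 of 476-498 days, and 0 passed in limma without any of the others. The 714-day male whose description gives 43 days is among these, and the lowest adjusted p was 0.171 without it.

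Ribosomal protein genes had a mean slope of -0.0426 per year in testis, with 63 of 71 below 0 (adjusted p = 0.00126, and adjusted p = 0.743 with an estimated correlation). Oxidative phosphorylation genes had a mean slope of -0.0315, with 52 of 67 below 0 (adjusted p = 0.0153, and adjusted p = 0.743 with an estimated correlation). No member of either list passed, over all features or adjusted over the list alone. Both calls were lost without replicate 2 of 714-743 days, which is the male whose age is in doubt. They were also lost without replicate 3 or 4 of 174-194 days. Ribosomal mean slopes ran from -0.0615 to -0.0246 when single males were left out. Adjusted over the list alone, 1 Leydig cell gene, 2 theca genes, 1 macrophage gene and 1 complement gene passed with negative slopes, among them Cyp17a1 (-0.20 ± 0.06), a steroid hydroxylase, and C1qa. Of the per-mouse list means, none differed between 714-743 and 174-194 days after adjustment over 10 lists. The proteasome had the smallest exact permutation p = 0.0317 (adjusted p = 0.238).

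The third comparison followed adult ovary from 169 to 733 days. In the main fit of all 15 females no feature passed in limma, and 1384 had an unadjusted p under 0.05. With the same females, array weights gave 1819 features and 1 spread over all 39 mice gave 231. Without the 481-day female 55 features passed, 36 with positive and 19 with negative slopes, 20 of them named. In that fit Poc5, a centriolar gene, rose by 0.61 ± 0.09 per year (adjusted p = 0.0351), from -1.02 ± 0.28 at 169-194 days to -0.13 ± 0.22 at 704-733 days (SD, n = 5 each). In females of 17-33 days, which this slope leaves out, Poc5 stood at -0.35 ± 0.12 (SD, n = 4), above the level at 169-194 days. The F-box gene Fbxw24 (0.48 ± 0.09), Zfp369 (0.38 ± 0.08), the autophagy gene Wipi2 (0.33 ± 0.06), Umodl1 (0.26 ± 0.05), Arel1 (0.22 ± 0.04), the prefoldin gene Pfdn4 (0.22 ± 0.04) and Pon3 (0.14 ± 0.03) rose too. The splicing gene Lsm3 fell by 0.32 (SE 0.05), the kinase gene Fyn by an estimate of -0.32 ± 0.06, the ribosomal gene Rps14 at -0.26 ± 0.05, the cell cycle kinase gene Cdk2 at -0.24 ± 0.05 and Syvn1 at -0.23 ± 0.04. Akr1c19 (-0.23 ± 0.04), the proteasome gene Psmc5 (-0.22 ± 0.03), the matrix gene Sparc (-0.21 ± 0.04), Mdn1 (-0.20 ± 0.03) and Tmtc4 (-0.18 ± 0.04) fell as well. With all 15 females the smallest p-values belonged to Poc5 (0.60 ± 0.11), Dnttip2 (0.32 ± 0.07), Fbxw24, Umodl1 and Timm50 (0.28 ± 0.07) above 0, and to Lsm3, Fyn, Rps14, Chaf1b (-0.27 ± 0.06) and Akr1c19 below 0, with adjusted p of 0.267 to 0.397.

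Ribosomal protein genes had a mean slope of -0.156 per year in ovary, with 66 of 71 below 0 and 1 passing when adjusted over the list alone, 43 without the 481-day female. Rpl9 (-0.30 ± 0.08) and Rpl7 (-0.28 ± 0.08) had the steepest slopes among the named members. The list had an adjusted p = 4.57e-16, and adjusted p = 0.555 with an estimated correlation. Oxidative phosphorylation genes had a mean slope of -0.0646 (adjusted p = 0.00909, adjusted p = 0.582 with an estimated correlation, and adjusted p = 0.0888 without the dimmest features). Granulosa cell genes had a mean slope of -0.0823, with 13 of 15 below 0 and 2 passing when adjusted over the list alone (adjusted p = 0.0388, and adjusted p = 0.405 with an estimated correlation). Those 2 were Hmga2 (-0.18 ± 0.05) and Kitl (-0.15 ± 0.05), the ligand of Kit, while Foxl2 (-0.13 ± 0.06), a granulosa transcription factor, did not pass. The granulosa list was no longer called without the 481-day female (adjusted p = 0.0841), or without replicate 1, 4 or 5 of 169-194 or of 704-733 days. The same held without the dimmest features (adjusted p = 0.0942), with array weights (adjusted p = 0.0940) and with 1 spread over all 39 mice (adjusted p = 0.104), with mean slopes from -0.0919 to -0.0725 when single females were left out.

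Per-mouse means compared the oldest ovaries with those of 169-194 days, which leaves out the 481-day female. They were tested for the 10 lists already called on these mice, so the p-values are not independent evidence. The ribosomal mean was 0.158 ± 0.082 against 0.388 ± 0.116 (SD, n = 5 each; exact permutation p = 0.0159, adjusted p = 0.0317). The granulosa mean was 0.117 ± 0.050 against 0.240 ± 0.032 (SD, n = 5 each). The spermatid mean was 0.0848 ± 0.0185 against 0.173 ± 0.039, and the proteasome mean -0.204 ± 0.031 against -0.126 ± 0.031. For these last 3 lists every older female lay below every younger one, with an exact permutation p = 0.00794, the smallest that 252 assignments allow (adjusted p = 0.0265). Camera called neither the spermatid list (adjusted p = 0.422) nor the proteasome (adjusted p = 0.350) in the slope of the 15 females. Oxidative phosphorylation differed as well, at -0.201 ± 0.028 against -0.104 ± 0.059 (exact permutation p = 0.0159, adjusted p = 0.0317). Theca and stroma, at -0.187 ± 0.113 against -0.0310 ± 0.0205, did not pass (exact permutation p = 0.0397, adjusted p = 0.0661).

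**Figure D3:**
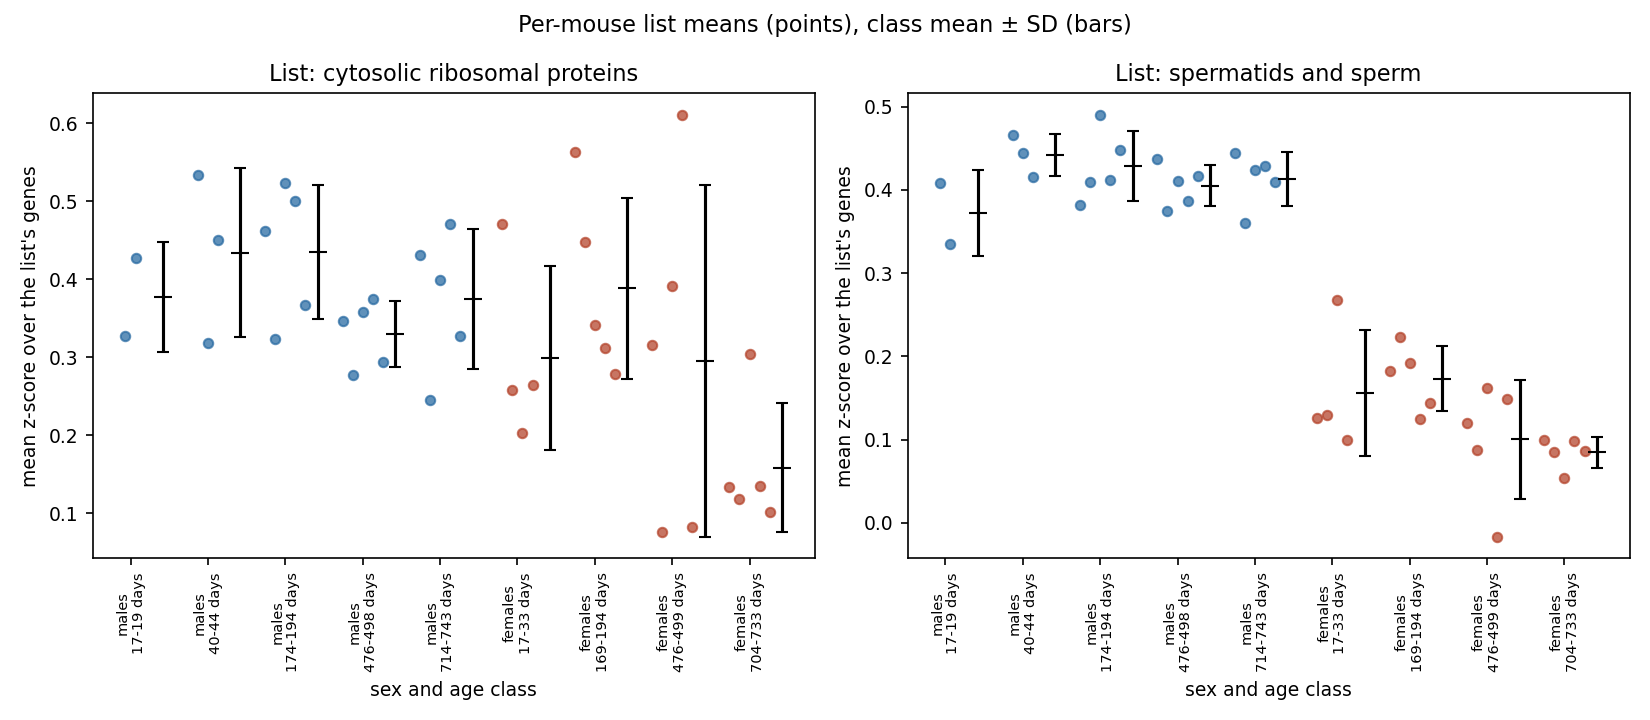
Mean z-score over the genes of the ribosomal protein list and of the spermatid and sperm list (vertical axes) by sex and age class (horizontal axes). Points are mice, blue for males and red for females, and bars give the class mean ± SD. The ribosomal mean is 0.388 in females of 169-194 days and 0.158 at 704-733 days, and the highest point is the 481-day female at 0.611.

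The fourth comparison asked whether the age slope differed between the sexes. No feature passed in limma with all 30 adults, and 742 had an unadjusted p under 0.05. The smallest p-values belonged to Poc5 (-0.65 ± 0.12, adjusted p = 0.122), Mat2b (-0.44 ± 0.09), Timm50 (-0.33 ± 0.07), the lysosomal protease gene Ctsd (-0.35 ± 0.08) and Dnttip2 (-0.40 ± 0.10), where the male slope was below the female one. In the other direction they belonged to the homeobox gene Otx2 (0.29 ± 0.07), Gtf3c3 (0.25 ± 0.06), Akr1c19 (0.22 ± 0.06), Cdk2 (0.24 ± 0.07) and Dnajc7 (0.18 ± 0.05). Without the 481-day female 10 features passed, 1 above and 9 below 0. The named ones were Poc5 (-0.66 ± 0.11, adjusted p = 0.0165), the collagen gene Col6a5 (-0.67 ± 0.13) and Wipi2 (-0.36 ± 0.07). Leaving out the female of 169-194 days, replicate 4, gave 3. Ribosomal protein slopes were on average 0.114 higher in males, with 63 of 71 above 0 and no member passing either way (adjusted p = 2.13e-07, and adjusted p = 0.732 with an estimated correlation).

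The fifth comparison set testes of 40-44 days against those of 17-19 days, on either side of the first wave of sperm formation. No feature passed in limma in the main fit, and 1296 had an unadjusted p under 0.05. No serial set held males of both classes, so class and set are confounded here, and the count rose with the set as a block. The smallest p-values above 0 belonged to Erdr1 (0.56 ± 0.11), the germ cell gene Tex14 (0.28 ± 0.06), Pidd1 (0.75 ± 0.18), Ces1d (0.27 ± 0.06) and Ppl (0.93 ± 0.22). Below 0 they belonged to the peroxisomal protease gene Lonp2 (-0.23 ± 0.05), Rasl2-9 (-0.51 ± 0.13), Akr1b10 (-0.61 ± 0.16), Tmem208 (-0.36 ± 0.09) and Rnf214 (-0.50 ± 0.13), with adjusted p of 0.424 to 0.461. The spermatid list stood at 0.372 ± 0.051 (SD, n = 2) and 0.442 ± 0.026 (SD, n = 3), and no list was called (smallest adjusted p = 0.445). Without the male of 40-44 days, replicate 2, 109 features passed, and without the male of 17-19 days, replicate 1 or replicate 2, 82 and 1 passed, with the remaining mouse of 17-19 days assumed to vary like the other classes.

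The sixth comparison set testes of 174-194 days against those of 40-44 days. No feature passed in limma, and 1187 had an unadjusted p under 0.05. The smallest p-values above 0 belonged to the mitochondrial ribosome gene Mrpl16 (0.20 ± 0.05), Abhd8 (1.87 ± 0.46), the retinal dehydrogenase gene Aldh1a1 (0.29 ± 0.07), Ube2e2 (0.36 ± 0.09) and Brd9 (0.36 ± 0.09). Below 0 they belonged to Ttpal (-0.42 ± 0.11), Erdr1 (-0.31 ± 0.09), Ces1d (-0.19 ± 0.05), Trp53inp1 (-0.31 ± 0.09) and Cep70 (-0.17 ± 0.05), all with an adjusted p = 0.601. No list was called (smallest adjusted p = 0.109). Adjusted over the list alone, 1 Leydig cell gene, 2 theca genes, and 1 gene each of the luteal, ovarian surface and smooth muscle lists passed, all higher at 174-194 days. Without the male of 40-44 days, replicate 2, 513 features passed.

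The seventh comparison set ovaries of 169-194 days against those of 17-33 days. No feature passed in limma, and 184 had an unadjusted p under 0.05, or 643 without the 481-day female, both below the 719.2 expected by chance. The smallest p-values above 0 belonged to the ribosome assembly gene Rsl24d1 (0.31 ± 0.09), the glycolytic gene Gapdh (0.33 ± 0.10), the G protein gene Gnb1 (0.41 ± 0.13), Bcas3 (0.34 ± 0.12) and Xpot (0.29 ± 0.10). Below 0 they belonged to Poc5 (-0.68 ± 0.15), Fbxw24 (-0.59 ± 0.16), Umodl1 (-0.26 ± 0.08), Zfp598 (-0.43 ± 0.13) and Mettl6 (-1.70 ± 0.56). Poc5, Fbxw24 and Umodl1 were also named for positive slopes in adult ovary. The class of 169-194 days enters both comparisons, so a low level in that class alone would give both results. Levels at 17-33 and 169-194 days were -0.345 and -1.02 for Poc5, 0.36 and -0.232 for Fbxw24, and -0.1125 and -0.372 for Umodl1. Ribosomal protein genes had a mean difference of 0.0895, with 62 of 71 above 0 (adjusted p = 2.34e-05, and adjusted p = 0.954 with an estimated correlation). Lysosomal genes had a mean of 0.0486, with 26 of 33 above 0, Gm2a (0.18 ± 0.08) and Lamp2 (0.21 ± 0.09) among them and Hexa at -0.94 ± 0.44 (adjusted p = 0.0332, and adjusted p = 0.0920 with an estimated correlation). No member of either list passed, alone or over all features. The ribosomal call was lost without replicate 1 of 169-194 days or replicate 3 of 17-33 days. The lysosomal call was lost without any 1 of these 9 mice except replicate 2 of 17-33 days, and without the dimmest features. When single mice were left out, the mean ran from 0.0458 to 0.147 for ribosomal proteins and from 0.0210 to 0.0671 for lysosome. Of the per-mouse means of 10 lists none differed after adjustment, with an exact permutation p = 0.294 for ribosomal proteins and p = 0.175 for lysosome (adjusted p = 0.730 each).

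The eighth comparison was the slope on age over all 39 mice, with sex as a covariate. No feature passed in limma, and 1230 had an unadjusted p under 0.05, or 2297 without the 481-day female, where again none passed. The smallest p-values below 0 belonged to the chromatin assembly gene Chaf1b (-0.14 ± 0.03), the histidine methyltransferase gene Setd3 (-0.14 ± 0.03), the ATP synthase gene Atp5g2 (-0.097 ± 0.021), Abhd13 (-0.098 ± 0.022) and the chaperonin gene Cct3 (-0.12 ± 0.03). Above 0 they belonged to the hyaluronan receptor gene Cd44 (0.12 ± 0.03), Prmt8 (0.14 ± 0.04), Frat2 (0.10 ± 0.03), Nufip2 (0.088 ± 0.025) and Nsun3 (0.10 ± 0.03), with adjusted p of 0.187 to 0.300. Members with slopes below 0 numbered 64 of 71 for ribosomal proteins (adjusted p = 1.99e-15), 52 of 67 for oxidative phosphorylation (adjusted p = 4.14e-05) and 41 of 62 for chaperones (adjusted p = 0.0124). They numbered 29 of 38 for the proteasome (adjusted p = 0.0400) and 12 of 14 for theca and stroma (adjusted p = 0.0327), and each of these 5 lists had an adjusted p = 0.315 with an estimated correlation. No member passed over all features, and 7, 1, 5, 2 and 1 did, in this order, when adjusted over the list alone, all below 0. The steroid hydroxylase gene Cyp17a1 led the theca list at -0.17 ± 0.05. The theca and stroma list was no longer called without the 481-day female (adjusted p = 0.0893), or without replicate 2 of 17-33 or of 704-733 days. The theca call was also lost with array weights and without the mice under 100 days. The chaperone call was lost without replicate 2 of 704-733 days and without the mice under 100 days. The proteasome call was lost without any 1 of 6 mice. These were males of 476-498 and 714-743 days, replicate 1, of 714-743 and 17-19 days, replicate 2, and females of 704-733 days, replicates 2 and 5. Among them, replicate 2 of 714-743 days is the male whose age is in doubt. The proteasome call was lost too with quantile normalization (adjusted p = 0.0531), array weights or the logarithm of age, and without the dimmest features or the mice under 100 days.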

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

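Of the tests on the 481-day female, those of a testis sample under a female label and of the slope on the testis minus ovary difference were chosen only after the result was seen.

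The arrays of the 481-day female (females of 476-499 days, replicate 4) correlated with other female arrays with a median r of 0.698 on membrane A and 0.749 on membrane B, and 18 of its 30 list means lay outside the range of the other 18 females. Its median r with the male arrays was 0.7675 and 0.8007, higher than with the females. No male lay under 0.960 and 0.961, which argues against a testis sample like the other males under a female label. A testis array of poor quality would miss that bar too, so the test cannot decide on one. The label genes went both ways. Eif2s3y at -0.01 lay above every other female (highest -0.06) and within the males (-0.42 to 0.02). Uty at -1.75 lay within the other females (-2.15 to -1.22) and within the males (-2.35 to -1.61). Xist at -0.39 lay above every other female (highest -0.66) and male (highest -1.09). A change of scale is argued against by its rank correlations of 0.7674 and 0.768, where no other female lay under 0.947 and 0.961. Noise of each membrane passed a test written beforehand, since the deviations of 963 genes on both membranes correlated with r = 0.014 and 337 of 1000 random re-pairings of the genes were as high, but the other 14 adult females lay from -0.0529 to 0.128, so this test separates little. In the later test the deviations followed the testis minus ovary difference of mice under 100 days with slopes of 0.8509 and 1.081, or 0.939 and 1.15 before a term for the level was added after that first form had been seen, while no other adult female exceeded 0.303 and 0.288, which argues against such noise as the whole cause. Slopes of that size would also go with a testis sample. A testis sample of poor quality, a mixture with another tissue, signal left on a reused membrane and a difference of the mouse itself stay open. Its spermatid mean of -0.0167 lay below the 0.0539 to 0.267 of the other females and the 0.336 to 0.491 of the males. Its meiotic spermatocyte mean of 0.464 lay above the highest of the other females, 0.285, and within the males (0.358 to 0.478). Its collagen mean of 0.441 lay above the highest of the other females, 0.141, and of the males, also 0.141. Other means above both sexes included ovarian surface cells at 0.223 (highest female 0.0983, male 0.108), and oviduct and uterus at 0.00681 (-0.206 and -0.154). Macrophages at 0.216 (0.113 and 0.000357) were above both as well. Its complement mean of -0.419 lay below both (lowest female -0.303, male -0.306).

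Within classes of 4 or 5 mice, 13 of 210 list means had 1 mouse far from the others by Dixon's criterion, 3 of them the 481-day female, where chance gives about 10.5. Among levels of named genes this held for 52 of 553, 16 of them the 481-day female, where chance gives about 27.65. The ribosomal protein slopes differed between the sexes, with a mean male minus female slope of 0.114 per year in the camera test of the difference at the preset correlation, which was lost with an estimated correlation (adjusted p = 0.732).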

How the results depend on the processing

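Leaving out the 481-day female was chosen only after the data were seen. Without it the sex difference counted 9095 features, the female trend 55 and the difference of the slopes 10. With array weights the counts were 9315 for the sex difference, 2 for the male trend, 1819 for the female trend, 54 for the difference of the slopes, 1304 for males of 174-194 against 40-44 days and 1 for females of 169-194 against 17-33 days. With 1 spread over all 39 mice they were 0 for the male trend, 231 for the female trend and 1 for the difference of the slopes. The male trend had 0 with quantile normalization (smallest adjusted p = 0.0503), 0 without the dimmest features and 2 for the oldest minus the youngest adult class. Leaving out 1 mouse at a time gave 5615 to 9095 for the sex difference, 0 to 2 for the male trend, 0 to 55 for the female trend, 0 to 10 for the difference of the slopes, 0 to 109 for males of 40-44 against 17-19 days, 0 to 513 for males of 174-194 against 40-44 days, and 0 for the ovary step and the slope over all mice. The cause was not tested in any of these, except that fewer mice enter.

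Mice of the same serial set shared little, with mean correlations of deviations of 0.0355 to 0.0794 within sets and -0.0152 between them. The mean was above 0 in each of the 5 sets, and what a set shares besides its numbers is not known here. With the set as a block, males of 40-44 against 17-19 days gave 222 features, 181 higher and 41 lower. No set holds both of these classes, so the block compares them only through the other males of their sets. No other count moved by over 1.5 times. The block ended 3 list calls, those of luteal genes in the sex difference (adjusted p = 0.0722), lysosome in the ovary step (adjusted p = 0.0537) and theca and stroma in the slope over all mice (adjusted p = 0.0535).

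Of 2503 values of named genes under the alternatives, 2416 kept their direction and side of the threshold, 13 lost the threshold, 74 gained it and 0 turned. The named genes of the sex difference had all passed in the main fit, and every value of theirs kept both. The losses were all in the male trend, where only Erdr1 had passed. The remaining named genes had not passed, so a kept side means only that they again did not pass. For them the pooled count does not show a stable difference. Of 717 values of called lists, 632 kept both, 85 lost the threshold and 0 turned. Every called list except spermatids and lysosome in the sex difference lost it with an estimated correlation. Fry called 22 of 30 lists in the sex difference, where camera at the preset correlation called 7, and 3 in the female trend, where camera called 3. It called 0 in the main fit of every other comparison, where camera called 2 in the male trend, 1 in the difference of the slopes, 2 in the ovary step and 5 in the slope over all mice. Without the 481-day female fry called 22 in the sex difference, 10 in the female trend, 0 in the difference of the slopes, 1 in the ovary step and 11 in the slope over all mice. Camera at the preset correlation then called 5, 2, 1, 2 and 4 in this order. An offset before the logarithm was not run, since the deposited scores are standardized. Signal over background is not known here, so the limit it sets is open.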

Other observations

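The family tests, the tests of the young testis, the leaving out of the 481-day female and the use of unadjusted p in the regroupings were chosen only after the results were seen.

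Of 33 measured genes named for cilia and the axoneme, the core of the sperm tail, 16 passed higher in adult testis than in ovary and 3 lower, in a family put together after Rsph, Cfap and Tekt genes had been seen. The radial spoke genes Rsph3a (1.26 ± 0.05) and Rsph1 (0.55 ± 0.05), Cfap36 (1.22 ± 0.06), and Ift74 (0.85 ± 0.06) and Ift46 (0.72 ± 0.06) of intraflagellar transport were higher, while Spag7 (-0.41 ± 0.12) and the dynein gene Dnah5 (-0.66 ± 0.24) were lower (SE, 15 males and 15 females). Camera with an estimated correlation gave p = 0.001367 for all 33, which restates the genes that prompted it. With the Rsph, Cfap and Tekt genes left out, 21 remained, 7 higher and 3 lower. Camera with an estimated correlation then gave p = 0.1141, so a difference of the family as a whole was not shown. Nuclear transport genes, tested for the same reason after Ran, had 13 of 40 higher and 5 lower, with Kpna2 at 1.22 ± 0.07 and Xpo4 at -0.73 ± 0.09. Camera with an estimated correlation gave p = 0.2574, and p = 0.4853 without Ran, so no difference of the group was shown.

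Between testes of 17-19 and 40-44 days no feature passed in the main fit. Without the male of 40-44 days, replicate 2, 109 passed, and the count also rose with the serial set as a block. Class and serial set are confounded in this comparison. Simulated shifts of 0.25 were recovered in 5.88%, so differences of that size can be missed. At 17-19 days the spermatid list lay nearer to adult testes than to adult ovaries. Of its adult testis minus ovary difference 0.8521 was already present, from 0.729 to 0.975 in the 2 mice. For the 200 features with the strongest testis-high statistics the median share was 0.990, with a 10th percentile of 0.830. With 9 of 54 listed genes measured and 2 mice, this cannot exclude that transcripts of late germ cells were still missing at that age. Clones that read other sequences than the gene they are named for may account for the small difference of that list, since 2 clones of a gene shared little of their sex difference (r = 0.3041 on membrane A and 0.2066 on membrane B, across genes, which are not independent replicates). That low agreement could also come from noise, and ages recorded wrongly were not tested.

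Features higher in testis had lower age slopes in ovary, with r = -0.472 across 14384 features and 14 females without the 481-day female, and in testis r was -0.344. Noise shared by both measures is argued against by r = -0.3948 with the sex difference taken from mice under 100 days. With the serial set as a block r was -0.4747. Each set holds about 1 mouse of each adult class, so the block could hardly move the slopes and cannot decide on the sets. Within a set the numbers rise with the age class, so that order cannot be told apart from age. Few permutations of the ages gave an r as far below 0 in ovary (permutation p = 0.00388), while in testis, with r = -0.256 for the same mice under 100 days, chance could not be excluded (permutation p = 0.07624), and the ovary was not shown to differ from the testis. With quantile normalization r was -0.393 and with scaling by the median and median absolute deviation -0.384, and features are not independent replicates. A change of cell composition with age is a candidate explanation that was not tested.

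Random regroupings of the same mice were counted beside each real count. For the sex difference 1 of 100 splits, the real one with 6054 features, called as many, and the highest other called 4, so chance can be excluded. The female trend without the 481-day female had 55, reached by 1 of 100, with 1 in the highest other. That mouse was left out after the data were seen, and the splits do not repeat this choice, so chance is not excluded. For the male trend 4 of 100 called at least the 1 feature found, a share near what the adjusted threshold of 0.05 allows by itself, so it adds nothing to that call. Since 14 of 100 had as many features with an unadjusted p under 0.05 as the real 1136, and the highest other called 101, chance is not excluded for the male trend. Counts of 0 are reached by every split, 100 of 100 or 56 of 56, and so decide nothing about chance. Those were the female trend (highest other 387), the difference of the slopes (4), the ovary step (0), the slope over all mice (0) and males of 174-194 against 40-44 days (858). By features with an unadjusted p under 0.05, as many were reached by 6, 26, 39 and 7 of 100 and by 15 of 56 splits in this order, so chance could not be excluded there. The values of 101, 387 and 858 point to a structure of the samples or to features that move together, and the cause was not tested. Without the 481-day female the highest other of the female trend was 1 instead of 387, over splits drawn anew.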
